A study of Bos taurus with 6 samples.

How the data were processed

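Genomic DNA from blood of 6 adult male cattle was cut with MspI, size selected, bisulfite converted and amplified by PCR, per the labels' protocols. The labels also state that the Creole and Spanish DNA were extracted with different commercial kits and that the ends left by MspI were filled in during library preparation. Trim Galore, Bismark and methylKit and the genome build UMD3.1 are named in the submitters' processing notes. Their roles, versions and settings, the handling of PCR duplicates, and the caller and thresholds behind the table of regions are not given in the sources used here.

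For each library, the deposited coverage file holds the count of methylated and of unmethylated read calls at each covered CpG cytosine, not normalized. The percent column deposited beside the counts equals methylated calls over all calls in every line of all 6 libraries, and was recomputed from the counts. Strands are kept apart in the deposited counts. The deposited file of Creole 1 covers the chromosomes and no unplaced scaffolds, while the other 5 also cover scaffolds. Scaffold calls entered no comparison. The authors' table of differentially methylated regions gives, per the file headers, the mean methylation of each group as a fraction (multiplied into percent here), their difference, a score per region (the area statistic), the length, the number of CpGs, and the relation to genes and CpG islands. The score was used in no comparison. The table holds 0 columns of single samples.

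Groups were taken from the breed labels, with the Sanmartinero and Costeno con Cuernos animals as Creole and the Retinta, Asturiana de los Valles and Lidia animals as Spanish. Replicate numbers follow the order of the samples and pair no animals across groups. Extraction kit, lane mark and group coincide, so no covariate for them could enter a model.

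The mean methylation of a library was taken over cytosines with at least 10 reads in every library, each cytosine weighted equally, and compared by an exact two-sided permutation test over the 10 splits of 3 against 3, whose smallest p is 0.10. Windows of 1000 bp on a fixed grid summed the calls of cytosines covered in all 6 libraries, and needed 3 such cytosines and 10 calls in every library. A window held a median of 9 such cytosines and 478 calls per library. Windows, single cytosines and deposited regions were tested with edgeR 4.0.16 (quasi-likelihood F test on methylated and unmethylated counts, library effects in the design, dispersion without trend, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. Alternatives were edgeR's likelihood ratio test, limma 3.58.1 on the log2 ratio of methylated to unmethylated counts with 2 added to each, and a likelihood ratio test on pooled reads without variance between animals. Other alternatives changed the read minimum to 5 or 20, thinned all libraries to equal depth, capped coverage at the 99.9 percentile, used autosomes alone, merged strands, changed window size to 500 or 2000 bp, shifted the grid by 500 bp, or left out each library in turn. Positions that could carry filled-in cytosines were removed in an alternative added after the data were seen, as was the demand for only 1 or more, or 2 or more, libraries per group.

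Deposited regions were recomputed as methylated over all calls within the region, for each library with at least 10 calls there, and averaged over the libraries of a group. A value from 1 library is given with its 95% Wilson interval, except where the values of several regions are given as a range. Fisher's exact test (scipy 1.17.1) compared features between regions of opposite direction. In Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining tables and plots.

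The rule for naming loci was fixed before the data were examined: windows past the threshold without overlap between groups, or, with fewer than 10 of these, the 10 windows of smallest p in each direction; the 10 deposited regions with a gene name (read as a symbol or UniProt entry name) and the largest listed difference in each direction; and members of 17 gene lists. Loci outside this rule are marked as such. A locus that the rule names is not reported here. Gene names are those of the authors' table. Symbols and UniProt entry names were looked up in a RefSeq gene list of the assembly ARS-UCD2.0, used for names only, where 87 of 90 regions with a symbol and 15 of 37 with a UniProt entry name matched a gene on the same chromosome. Tests of promoters by gene list and levels in promoter, exon and intron sequence need an annotation of UMD3.1 and were not run. The lists were matched to the names in the authors' table in their place. Levels of imprinted and germline promoters, planned as a check, were not run for the same reason. Mitochondrial cytosines, of which the coverage files hold 0, gave no bound on bisulfite conversion.

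The window test was tested on simulated data with the windows and depths of the real libraries and, short of the extremes, their mean levels in unchanged windows. The windows changed by 25 points (100) and by 50 (100) started from a fixed level in place of their own. All windows were given the same spread between animals. At the spread observed over all windows (intraclass correlation 0.0774) the test called 1 and 5 of the changed windows and 0 of 4502 unchanged windows, and 4.82% of unchanged windows had an unadjusted p under 0.05. At a spread of 0.02 it called 48 and 99, with 14 false calls.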

Results

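Blood DNA of 6 adult male cattle from 5 breeds was profiled by reduced representation bisulfite sequencing, in which genomic DNA is cut at CCGG sites by MspI, treated with bisulfite and sequenced, so that unmethylated cytosines read as thymine. The Creole group held 1 Sanmartinero animal (Creole 1) and 2 Costeno con Cuernos animals (Creole 2 and Creole 3). The Spanish group held 1 Retinta (Spanish 1), 1 Asturiana de los Valles (Spanish 2) and 1 Lidia animal (Spanish 3). The question was whether methylation in blood differs between Creole cattle, which live in the American tropics, and the Iberian breeds from which they descend. The labels set 1 library for each animal, so the spread within a group is the spread between animals, and in both groups also between breeds.

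Total CpG read calls were 84537374 in Creole 1, 54313504 in Creole 2, 44681983 in Creole 3, 40986296 in Spanish 1, 44950051 in Spanish 2 and 46716142 in Spanish 3. These calls covered 3491869, 858369, 710684, 1079903, 1692031 and 1000362 cytosines, with medians of 8, 19, 13, 10, 16 and 19 reads per cytosine in the same order. The libraries shared little of the genome: of 4663216 cytosines covered on the chromosomes, 2393476 were covered in 1 library only and 22289 had at least 10 reads in all 6. The Creole DNA was extracted with another kit than the Spanish DNA and carried another lane mark, so kit, lane and group cannot be told apart in any comparison.

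At the ends of covered stretches, the 2 strands of a CpG read differently in every library. The strand that library preparation would fill in read 3.22% to 6.50% on average over the libraries, and its partner strand 69.3% to 74.3%. Without such cytosines the difference between the group levels given further on was -1.18 points.

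**Figure D1:**
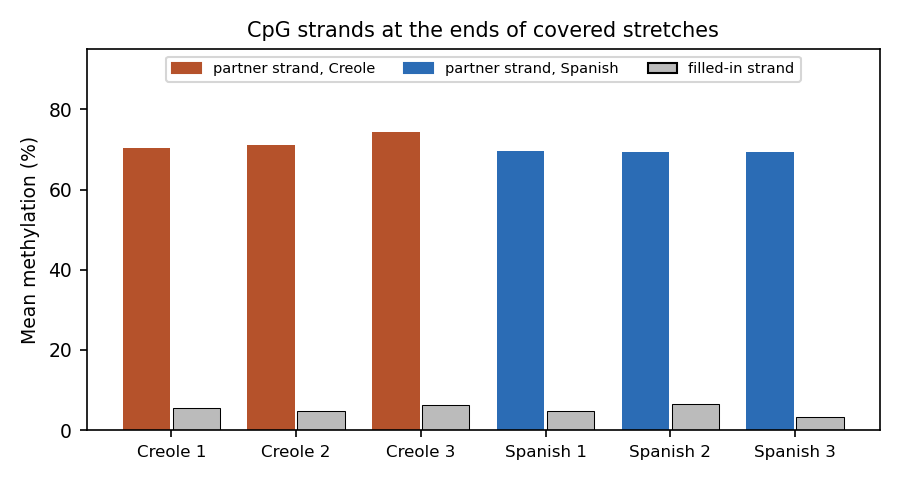
Mean methylation (percent, vertical axis) of both strands of CpGs at the ends of covered stretches in each library, with the partner strand in colour (Creole brown, Spanish blue) and the filled-in strand in grey. The grey bars lie between 3.22% and 6.50%, the coloured bars between 69.3% and 74.3%.

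Among regions listed with a gene symbol or a UniProt entry name, the 10 largest differences in each direction included regions in LATS2 and BLM, higher in Creole, and in PGRP1_BOVIN and LTBP3, higher in Spanish animals, per the authors' deposited table. In the authors' deposited table, a 61 bp region in an intron of LATS2, a kinase of the Hippo growth-control pathway, had mean methylation of 90% in Creole and 7% in Spanish animals (UMD3.1 chromosome 12, 35923079 to 35923139). An intronic region of BLM, a RecQ helicase of DNA repair, was listed in the authors' deposited table at 96% in Creole and 13% in Spanish animals (chromosome 21, 22267521 to 22267666). In the opposite direction, the authors' deposited table gave an exonic region of PGRP1_BOVIN, a peptidoglycan recognition protein of innate immunity, as 4% in Creole and 88% in Spanish animals (chromosome 18, 53947889 to 53947942). The authors' deposited table also placed LTBP3, which binds latent TGF-beta, among the regions higher in Spanish animals, at 13% against 91% over an intron-exon boundary (chromosome 29, 44390852 to 44390925).

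The authors' deposited table listed 334 regions, of which 236 were higher in Creole and 98 higher in Spanish animals. Per the authors' deposited table, they were 51 to 186 bp long (median 79.5 bp) with 4 to 50 CpGs (median 8), and each differed by at least 25 percentage points between the group means. Regions higher in Creole more often lay in the core of a CpG island, 87 of 236 against 11 of 98 in the authors' deposited table (odds ratio 4.62, two-sided Fisher's exact test p = 1.39e-06, Benjamini-Hochberg adjusted p = 5.56e-06 over 4 features). All 15 regions that the authors' deposited table placed on a promoter were higher in Creole, against 0 of the 98 higher in Spanish animals (Fisher's exact test p = 0.00723, adjusted p = 0.0145). Exon and intron overlap did not pass the same test in the authors' deposited table (adjusted p = 0.642 and 0.390). On the X chromosome, the authors' deposited table had 18 regions, and 16 of them were higher in Creole. In 173 of the 236 regions higher in Creole, the authors' deposited table gave a Spanish mean below 20%. The regions were selected as different between these same libraries, and Fisher's test treats them as independent.

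Recomputed from the coverage files, the regions higher in Creole had median group means of 84.2% in Creole and 2.80% in Spanish libraries, and those higher in Spanish animals 18.4% and 94.1%, over the libraries that covered them. The recomputed differences lay a median of 14.2 points from those of the authors' deposited table, and over 25 points from them in 42 of the 334 regions. BLM read 98.9% ± 0.443 (SD, n = 2) in Creole and 0.0% ± 0.0 (SD, n = 2) in Spanish libraries, from 35 to 411 read calls per library. TP53I11, a p53-inducible gene, read 99.92% ± 0.143 (SD, n = 3) in Creole libraries at an intronic region (chromosome 15, 75872398 to 75872498), and 0.0% in Spanish 3 alone (95% Wilson interval 0 to 1.68%, 225 calls). At LATS2 only Creole 1 had at least 10 calls, with 100% methylation (Wilson interval 97.1 to 100%, 128 calls) against 0.228% ± 0.395 (SD, n = 3) in the Spanish libraries.

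Among regions higher in Spanish animals, PGRP1_BOVIN read 0.745% ± 1.29 (SD, n = 3) in Creole libraries and 100% in Spanish 1 alone (Wilson interval 98.3 to 100%, 222 calls). LTBP3 read 0.719% in Creole 1 (Wilson interval 0.127 to 3.96%, 139 calls) and 96.8% ± 4.51 (SD, n = 2) in Spanish libraries. A region outside the gene CAH4_BOVIN, a carbonic anhydrase, read 0.0% ± 0.0 (SD, n = 2) in Creole 2 and 3 (chromosome 19, 13129013 to 13129076). Spanish 1 and 2 read 87.5% ± 0.0 (SD, n = 2) there. Calls were 2139 in Creole 2, 28 in Creole 3, 256 in Spanish 1 and 16 in Spanish 2. With 16 calls, Spanish 2 had a Wilson interval of 64.0 to 96.5%, so the SD of 0.0 does not show close agreement. Within-group spread was wide at other loci: near the growth factor gene PDGFA, Creole 1 read 66.7% (Wilson interval 39.1 to 86.2%, 12 calls) and Creole 2 read 0.0% (0 to 6.02%, 60 calls), against 100% in Spanish 2 (94.0 to 100%, 60 calls). A region listed as CRLF2, the symbol of a cytokine receptor gene, lay on chromosome 29 (50373133 to 50373222). The RefSeq gene list had no gene of that symbol on that chromosome. The Creole mean there was 25.03% ± 35.4 (SD, n = 2) and the Spanish mean 90% ± 14.1 (SD, n = 2). The Wilson intervals treat every call as independent. Calls summed over the cytosines of a region can share a read, and PCR reads without molecular identifiers are not independent molecules. The intervals may therefore be too narrow, and they do not cover the spread between animals.

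Other regions named by the rule had recomputed differences in the same direction as listed. Regions within PD2R_BOVIN, T4S5_BOVIN and SNX13, and regions outside the genes BRAT1, FCF1_BOVIN and CY561_BOVIN to which they were assigned, were higher in Creole. Creole values lay between 37.0% for PD2R_BOVIN and 100% for T4S5_BOVIN and SNX13, and Spanish values between 0.0% and 4.79%. Creole 1 was the only Creole library at PD2R_BOVIN, T4S5_BOVIN, FCF1_BOVIN and CY561_BOVIN. A single Spanish library was measured at BRAT1, SNX13 and CY561_BOVIN. For the prostaglandin D2 receptor gene PD2R_BOVIN, the 37.0% of Creole 1 alone (Wilson interval 32.1 to 42.3%, 343 calls) stands against a Creole mean of 89% in the authors' deposited table. Regions within PAPLN and TNRC18, and regions outside the genes TMEM179, bta-mir-2284p and PRKAR1B, were higher in Spanish animals. Spanish values lay between 95.4% and 100% and Creole values between 0.0% and 9.20%. Creole 1 was the only Creole library at TMEM179, PAPLN, bta-mir-2284p and PRKAR1B, and Spanish 2 the only Spanish library at TNRC18.

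All 334 regions had at least 10 read calls in 1 or more libraries of each group, and in all 334 the recomputed difference had the listed sign, which is not independent evidence because the regions were chosen on these libraries. Replication was thin: 76 regions were measured in 2 or more libraries per group, and 47 of these had no overlap between the groups. Any gap counted, as at GRM5, where Creole 2 read 99.88% and the Spanish libraries 100%. In 204 regions a single Creole library was measured, and in 178 that library was Creole 1. Creole 1 had at least 10 calls in 297 of the regions, Creole 2 in 115 and Creole 3 in 90, while Spanish 1, Spanish 2 and Spanish 3 had them in 200, 260 and 196. Without Creole 1, 156 regions could still be measured in both groups, and 142 of these (91.0%) kept the listed sign.

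**Figure D2:**
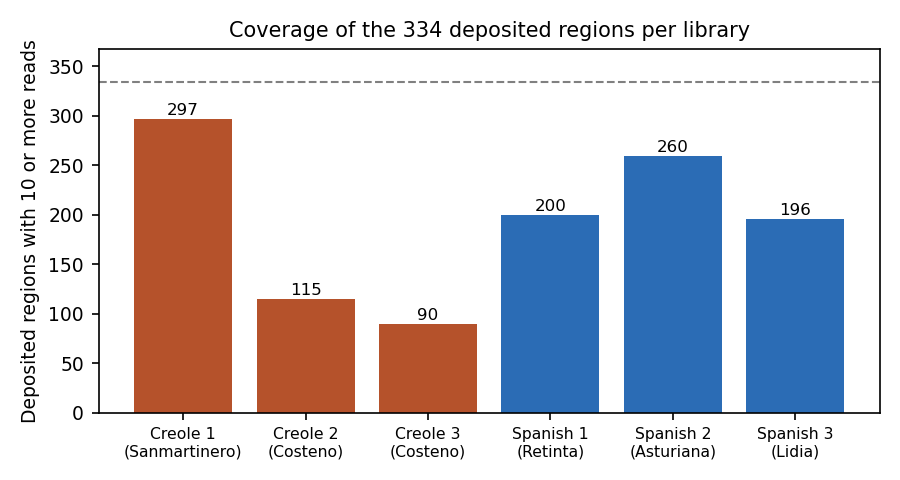
Number of the 334 deposited regions with at least 10 read calls in each library (vertical axis), with Creole libraries in brown and Spanish libraries in blue, and the dashed line at 334. Creole 1 measured 297 of the regions, against 115 and 90 for the other Creole libraries.

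The 8 regions measured in all 6 libraries allowed the groups to be compared with every animal. They are reported for that reason and not by the naming rule. A region without a listed gene on chromosome 1 (90311237 to 90311307) read 22.4% ± 27.4 in Creole and 98.8% ± 2.01 in Spanish libraries (SD, n = 3 each). Near FMN1, a formin that organises actin, Creole libraries read 81.5% ± 2.66 and Spanish libraries 35.6% ± 33.6 (SD, n = 3 each, chromosome 10, 29660517 to 29660659). These 2 regions had no overlap between groups; chance gives 10% among unselected regions, but these were selected as different on the same libraries. A region outside SP8, a limb and neural transcription factor gene, read 35.8% ± 31.5 in Creole and 8.66% ± 14.8 in Spanish libraries (SD, n = 3 each), an exonic region of CXXC5_BOVIN 55.7% ± 43.2 and 94.8% ± 9.02, and a region on chromosome 20 (70273957 to 70274052) 95.8% ± 7.20 and 53.9% ± 40.0, all with overlapping libraries.

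SHOX2, NRXN2 and SERPINB1 were the 3 regions with enough reads at cytosines shared by all 6 libraries to enter the test, and they are named for that reason and not by the naming rule. A region outside the homeobox gene SHOX2 read 34.5% ± 7.35 in Creole and 19.4% ± 16.2 in Spanish libraries (SD, n = 3 each, adjusted p = 0.806, edgeR quasi-likelihood test). NRXN2, a neurexin of synapses, read 43.4% ± 27.6 and 9.23% ± 13.7 (adjusted p = 0.371), and the serpin gene SERPINB1 71.6% ± 29.4 and 80.4% ± 20.3 (adjusted p = 0.875). The authors' deposited table lists wider gaps for these 3 regions, but for whole regions and not only for the shared cytosines tested here. Its Creole and Spanish means were 83% and 19% for SHOX2, 85% and 12% for NRXN2, and 31% and 92% for SERPINB1. No region passed at an adjusted p of 0.05: edgeR's quasi-likelihood test called 0 of 3, with 0 at an unadjusted p under 0.05, the likelihood ratio test 0, limma 0, and pooled reads without animal-to-animal variance 3. A read minimum of 5 gave 1 call among 5 regions.

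Of 17 gene lists fixed before the data were examined, 7 had a region matched by name, 1 each. DNMT3A, the de novo DNA methyltransferase, was listed in the authors' deposited table at 94% in Creole and 15% in Spanish animals for an intronic region (chromosome 11, 74042792 to 74042887). The recomputed values at DNMT3A were 100% ± 0.0 in Creole 2 and 3 and 0.0% ± 0.0 in Spanish 2 and 3 (SD, n = 2 each), from 10 to 419 calls per library. From the coat and pigmentation list, KIT_BOVIN, the receptor tyrosine kinase of melanocytes and mast cells, had a promoter region 58 bp before the gene start (chromosome 6, 71796198 to 71796260). Creole 1 read 60.0% there (Wilson interval 40.7 to 76.6%, 25 calls), against 0.758% ± 1.31 (SD, n = 3) in the Spanish libraries. HOXD11, of the HOX list, read 72.7% in an exon in Creole 1 (Wilson interval 67.6 to 77.3%, 319 calls) and 0.0% ± 0.0 (SD, n = 2) in Spanish libraries.

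Members of 3 lists were higher in Spanish animals. GRM5, a metabotropic glutamate receptor from the behaviour list, had an exonic region with 38 CpGs (chromosome 29, 7239598 to 7239744) that read 100% ± 0.0 (SD, n = 2) in Spanish libraries. Among the Creole libraries GRM5 split, with 10.4% in Creole 1 (Wilson interval 7.76 to 13.7%, 405 calls), 99.88% in Creole 2 (99.3 to 100%, 864 calls) and 0.0% in Creole 3 (0 to 2.34%, 160 calls). Near CD5_BOVIN, a T cell surface glycoprotein, methylation was 1.02% ± 1.44 (SD, n = 2) in Creole libraries and 42.3% in Spanish 2 (Wilson interval 36.6 to 48.3%, 274 calls). KCNQ1, a potassium channel gene of an imprinted domain, had a region outside the gene coordinates listed for it. Creole 1 read 53.4% there (Wilson interval 46.0 to 60.6%, 178 calls) and the Spanish libraries 98.3% ± 2.33 (SD, n = 3). No region matched by name the lists of heat shock and chaperone genes, innate sensing and cytokine genes, antigen presentation, or growth and energy metabolism. Nor did any match germline genes, housekeeping genes, or the markers of B cells, NK and cytotoxic cells, neutrophils and monocytes, and erythrocytes and platelets. These absences concern names only. Regions listed by UniProt accession (99), Ensembl identifier (30) or locus identifier (19) could not be matched. The same held for entry names absent from the gene list, among them PGRP1_BOVIN of innate immunity. With 1 region per list, no list was tested for enrichment.

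Away from the deposited regions, methylation was compared in 1000 bp windows, where every named value below failed the adjusted threshold of edgeR's quasi-likelihood test. On chromosome 7 (6698001 to 6699000), 10 cytosines read 78.2% ± 3.27 in Creole and 0.145% ± 0.251 in Spanish libraries (SD, n = 3 each), a difference of 78.1 points (SE 1.90) with an adjusted p of 0.202 by edgeR's quasi-likelihood test. A window on the lower-coordinate side of DLX6, a homeobox gene of craniofacial and limb development, read 33.5% ± 9.28 in Creole and 1.83% ± 1.62 in Spanish libraries (SD, n = 3 each, chromosome 4, 14273001 to 14274000, adjusted p = 0.501 by the same test). This window holds part of a deposited region. On the X chromosome (84042001 to 84043000), Creole libraries read 35.5% ± 7.31 and Spanish libraries 84.0% ± 5.78 (SD, n = 3 each, adjusted p = 0.501). On chromosome 9 (38521001 to 38522000), a very deeply read window held 48 cytosines and 5363 to 22629 calls per library. It read 68.8% ± 2.95 in Creole and 79.7% ± 0.182 in Spanish libraries.

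Other windows were also among the 10 of smallest p in each direction. On chromosome 8 (104010001 to 104011000), 13 cytosines read 33.3% ± 18.0 in Creole and 0.0% ± 0.0 in Spanish libraries (SD, n = 3 each). In another window of that chromosome (23184001 to 23185000) the means were 58.4% ± 4.68 in Creole and 35.3% ± 2.54 in Spanish libraries, and on chromosome 11 (82549001 to 82550000) 58.9% ± 0.968 and 78.1% ± 2.11 (SD, n = 3 each). On chromosome 22 (55343001 to 55344000) all 3 Creole libraries read 100% and all 3 Spanish libraries 80% over 5 cytosines. The equal Spanish values rest on 40, 70 and 20 calls. With the cytosine of largest difference removed, the gap was 16.7 points, so 1 cytosine shared by all 3 Spanish libraries did not make it up. Of the 20 windows, 19 had no gene of the deposited table within 5000 bp, and genes were not assigned to them here. The window on chromosome 14 (67509001 to 67510000) read 0.054% ± 0.0940 in Creole and 12.5% ± 0.0 in Spanish libraries. Its Spanish values rest on 32, 48 and 16 calls over 16 cytosines, and that of Creole 3 on 16 calls. This window lost its direction when all libraries were thinned to equal depth (0.026 points).

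**Figure D3:**
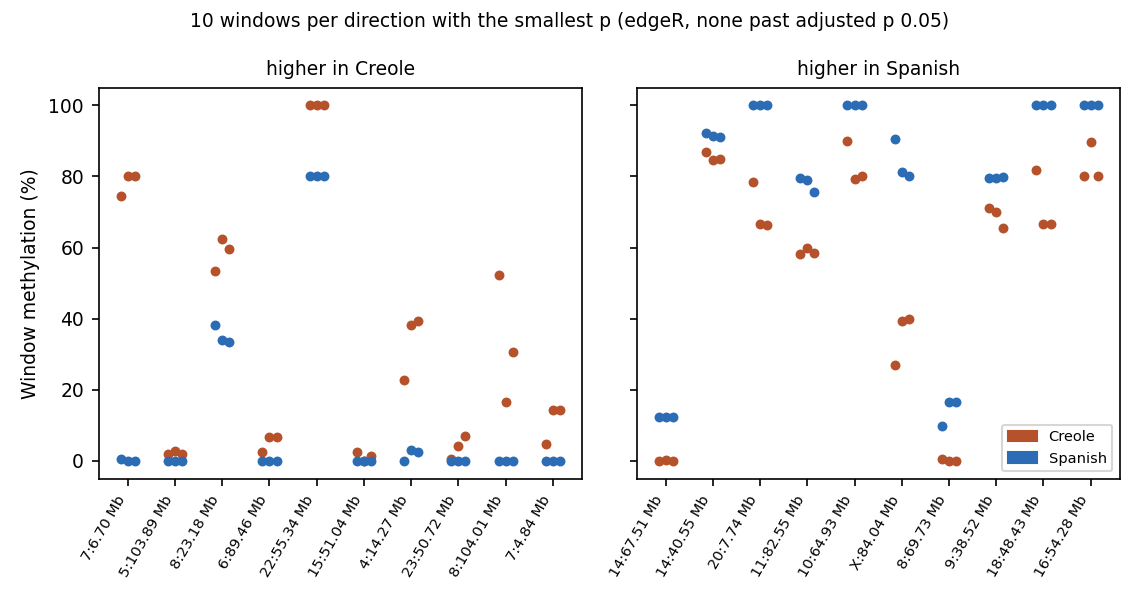
Methylation (percent, vertical axis) of each library in the 10 windows of smallest p higher in Creole (left) and higher in Spanish animals (right), each point 1 library, Creole in brown and Spanish in blue. The first window on the left, on chromosome 7, has the widest gap, 78.2% against 0.145%, and no window passed an adjusted p of 0.05 by edgeR's quasi-likelihood test.

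Of 4702 windows with at least 3 cytosines and 10 calls in every library, 4672 were tested, and edgeR's quasi-likelihood test called 0. At an unadjusted p under 0.05 there were 252 windows, 89 higher in Creole and 163 higher in Spanish animals. They were 5.39% of those tested, where a share of 0.05 is expected without any difference. The edgeR likelihood ratio test called 58 windows, limma 1, and pooled reads without animal-to-animal variance 3219. The groups did not overlap in 618 windows (13.1%, where chance gives 10%, and 339 to 481 windows in the other 9 splits of the libraries), 180 higher in Creole and 438 higher in Spanish animals. Per cytosine, 0 of 21020 tested passed the quasi-likelihood test, against 62 by the likelihood ratio test, 0 by limma and 14785 by pooled reads. The quasi-likelihood test had 744 (3.54%) at an unadjusted p under 0.05, 206 higher in Creole and 538 higher in Spanish animals. In simulated data where every window had the same spread between animals, set to that observed over all windows, the test found 5 of 100 windows changed by 50 points. In that setting most changes of that size were missed at an adjusted p of 0.05 with 3 animals per group. At a smaller spread of 0.02 it found 99 of 100, with 14 false calls, so detection depended on the spread assumed.

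Mean methylation over the 22289 cytosines shared by all libraries was 67.7% ± 0.582 in Creole and 68.8% ± 0.267 in Spanish libraries (SD, n = 3 each). The difference of -1.11 points (SE 0.370) left no overlap between the groups, with an exact two-sided permutation p of 0.10, the smallest that 3 against 3 can give. At the shared cytosines, median depth was 377, 209 and 171 reads in Creole 1 to 3. It was 100, 144 and 119 reads in Spanish 1 to 3. At each library's own cytosines with at least 10 reads, the medians were 20, 54, 65, 19, 24 and 44 in the same order. The level, single-cytosine and correlation results thus rest on unusually deep cytosines, and windows likewise used only cytosines covered in all 6 libraries. Why these were read so deeply was not tested. Creole means were lower on 27 of 30 chromosomes. On the X chromosome they were 73.5% ± 1.20 against 75.7% ± 0.437 (SD, n = 3 each, exact permutation p = 0.10), and on the autosomes 67.5% ± 0.560 against 68.5% ± 0.280. The sign turned when reads were pooled so that deep cytosines weighed more (0.159 points, exact permutation p = 1.0).

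When each library's own cytosines with at least 10 reads were averaged, the order of the groups was the opposite. Creole libraries then read 55.2% ± 1.75 and Spanish libraries 51.9% ± 1.08 (SD, n = 3 each, exact permutation p = 0.10). The groups also differed in which cytosines they covered. Windows with 60 or more covered cytosines per 1000 bp held 21.1% of own cytosines in Creole and 23.8% in Spanish libraries. Windows with fewer than 20 held 34.9% and 30.6% (exact permutation p = 0.10 for each share, n = 3 each). In CpG-dense windows with 60 or more covered cytosines per 1000 bp, own cytosines read 35.1% ± 1.86 in Creole and 28.7% ± 1.54 in Spanish libraries (exact permutation p = 0.10, n = 3 each), while shared cytosines of the same windows read 67.2% ± 0.822 and 67.8% ± 0.436 (exact permutation p = 0.5, n = 3 each). Own cytosines in windows with 20 to 59 covered cytosines read 55.8% ± 0.855 and 53.7% ± 0.601 (exact permutation p = 0.10), and in windows with fewer than 20 the groups overlapped, at 66.7% ± 1.12 in Creole and 67.3% ± 1.83 in Spanish libraries (exact permutation p = 0.6, n = 3 each). Shared cytosines read 69.1% ± 0.681 in Creole and 70.3% ± 0.259 in Spanish libraries in windows with 20 to 59. With fewer than 20 they read 63.3% ± 0.475 and 65.4% ± 0.284 (exact permutation p = 0.10 for each, n = 3 each). Between a Creole and a Spanish library, on the cytosines that the pair shared, the Creole mean was lower in 7 of 9 pairs, with differences from -0.996 to 0.377 points.

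**Figure D4:**
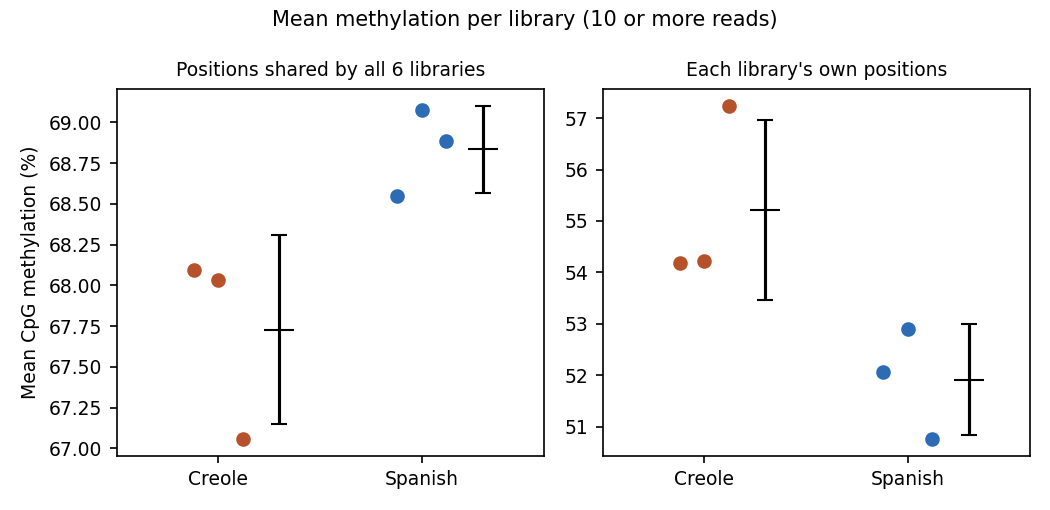
Mean CpG methylation per library (percent, vertical axis; the axes do not start at 0) over cytosines shared by all 6 libraries (left) and over each library's own cytosines (right), with points for libraries and bars for mean and SD (n = 3). Creole libraries lie below the Spanish ones on the left (67.7% against 68.8%) and above them on the right (55.2% against 51.9%).

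Averaged over pairs, libraries of one group correlated slightly better with each other than with the other group, but not in every case. The highest pair was Creole 1 with Spanish 2 (0.868). The Spanish pairs (0.758 to 0.809) lay on both sides of the mean between groups, 0.788. Pearson correlations across shared cytosines, which are not independent replicates, ran from 0.725 to 0.868 over the 15 pairs of libraries. The mean correlation within groups exceeded that between groups by 0.00569 (one-sided exact permutation p = 0.10, 1 of 10 splits as large). The 2 Costeno con Cuernos animals, of the same breed, correlated at 0.753 and ranked 13 of 15 among the pairs.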

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

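The tests of strand ends, of strands away from these ends, of template number, of Creole 1 standing apart, of bisulfite conversion and the splits for windows and cytosines were chosen only after the result was seen; the strand comparison within fully methylated or unmethylated CpGs and the splits of 100 bp bins were fixed before theirs.

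Unplaced scaffolds, which entered no comparison between the groups, carried methylated calls in all 5 libraries that cover them. The share of methylated calls was 77.0% in Creole 2 (95% Wilson interval 77.0 to 77.1%), 77.2% in Creole 3 (77.1 to 77.2%), 72.9% in Spanish 1 (72.8 to 73.0%), 78.2% in Spanish 2 (78.2 to 78.3%) and 75.9% in Spanish 3 (75.9 to 76.0%). No explanation was tested.

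CpGs at the ends of covered stretches had opposite methylation on their strands in every library. The strand that end repair would fill in read 3.22 to 6.50%, and its partner 69.3 to 74.3%. Few template molecules per strand are argued against, since at least 98.46% of discordant pairs had the predicted strand low. Fill-in with unmethylated cytosine at the MspI cut may account for the pattern, with a median deficit of 65.47 points over the libraries, and no biological explanation was tested. Removing such positions left the level difference at -1.18 points.

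Most cytosines with at least 20 reads were read as exactly 0 or 100%, 85.3 to 90.4% of them in the 5 libraries other than Creole 1 and 60.1% in Creole 1. At cytosines that were 30 to 70% methylated in Creole 1, at least 60.89% of values in each other library were exact, which is consistent with few template molecules amplified by PCR. Uniform methylation of the locus in that animal cannot be told apart from this. Both strands were exact in only 19 to 97 CpGs per library, and the strands disagreed in 15.79 to 48.65% of them, over the 20% set beforehand in 3 of 5 libraries and in 25.7% of all 241 (95% Wilson interval 20.6 to 31.6%). That bound and the 5% set for agreement took no account of other sources of disagreement: away from the ends of covered stretches it was 18.0% of 206 (13.3 to 23.8%), while pairs of strands there lay over 50 points apart in 17.6% of CpGs in Creole 1 as well. A difference in methylation between animals stays open as well, and was not tested apart from template number.

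More deposited regions were higher in Creole than in Spanish animals, and Creole 1 was the only Creole library in 178 of the 334. Incomplete bisulfite conversion in the Creole libraries is argued against, since the filled-in strand read at most 6.27% there. Creole 1 standing apart might add to the excess. This was judged on 100 bp bins of at least 4 cytosines in which 1 library lay over 50 points from every other. Of such bins, 75.3% were upward in Creole 1, 47.6% in Creole 2 and 47.9% in Creole 3. The share was lower in every Spanish library, at 35.6% in Spanish 1, 19.9% in Spanish 2 and 22.4% in Spanish 3. Yet the 37 regions without Creole 1 held 2.36 regions higher in Creole for each one higher in Spanish animals. That is 70.3% (exact 95% interval 53.0 to 84.1%), from too few regions to decide. Separated bins with 2 or more libraries per group numbered 381 in the real split (11.1 per 1000 bins) and 371 in the highest other split (9.38 per 1000), with 1 of 10 splits as large, and 10 splits are too few for a share under 0.05. Of the 381 bins in the real split, 249 were higher in Creole libraries and 132 lower. In 8 of 9 other splits as well, more bins were higher than lower in the libraries grouped with Creole 1. With Creole 1, Creole 3 and Spanish 1 together, the counts were 247 and 124. Creole 1 with Spanish 2 and Spanish 3 went the other way, at 126 and 167. The upward lean of bins was thus not limited to the real split. Each split was counted by the libraries grouped with Creole 1, so these counts cannot separate a lean of Creole 1 from one of the Creole group. Bins are also not the deposited regions. Breed, kit and lane coincide with the groups and remain open and untested.

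Windows past the threshold numbered 0 in the real split and 0 in the highest other split, so 10 of 10 splits were as large, and for single cytosines the counts were also 0 and 0 in 10 of 10. At an unadjusted p under 0.05, the real split gave 252 windows against 146 to 220 in the others, and 744 cytosines against 428 to 782. The 10 splits are too few for a share under 0.05.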

How the results depend on the processing

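Removing fill-in positions, requiring only 1 or more, or 2 or more, libraries per group, and leaving libraries out of the named regions and of the count of measured regions were chosen only after the data were seen; all other alternatives were fixed before the data were examined. The lower Creole level kept its sign in 13 of 14 alternatives; with each library left out it ranged from -1.29 to -0.771 points, and pooling reads reversed it to 0.159 points, which the weighting by depth sets. Windows past the threshold stayed at 0 in 18 further settings of the quasi-likelihood test (145 to 646 at an unadjusted p under 0.05) and with 2 or more libraries per group (2634 of 68649 at that p). They numbered 58 with the likelihood ratio test, 1 with limma and 3219 with pooled reads, a model that leaves out variance between animals. For single cytosines, 13 settings gave 0 (488 to 946 at an unadjusted p under 0.05), the likelihood ratio test 62, pooled reads 14785, and 2 or more libraries per group 47 of 85338. Deposited regions past the threshold numbered 0, but 1 of 5 at a read minimum of 5 and 3 with pooled reads. With 2 or more libraries per group it was 0 of 76, with 15 at an unadjusted p under 0.05. Except where the construction shows it, the cause was not tested. With each library left out, windows, cytosines and tested regions stayed at 0. Regions measured in both groups ranged from 156 (without Creole 1) to 321. The excess of correlation within groups was 0.00431 at a read minimum of 20 and 0.0236 for partly methylated cytosines. Of 198 alternatives for the 20 named windows, 197 kept the direction; the window on chromosome 14 from 67509001 turned to 0.026 points when thinned, and the cause was not tested. All 134 alternatives for the 26 named regions, each leaving out 1 library, kept theirs. Many left out a library without a value in the region, which could not change the difference. None could be run where the only library of a group was left out. Promoter tests by gene list and gene-class levels were not run under any setting. No paired analysis was possible because replicate numbers only name the animals. Depth limits the cytosines that all libraries share to 22289 at 10 reads and 15795 at 20.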

Other observations

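No test in this part was fixed before the data were examined, and the loci below were chosen after their values were seen, from the deposited regions measured in 2 or more libraries per group. The widest such gaps higher in Creole included SH3R1_BOVIN, at 95.9% ± 7.09 (SD, n = 3) in Creole and 0.0% ± 0.0 (SD, n = 2) in Spanish libraries (chromosome 8, 1034332 to 1034409). SMTNL1, a smoothelin-like muscle gene, read 96.8% ± 2.82 in Creole and 6.25% ± 8.84 in Spanish libraries (SD, n = 2 each). Of the promoter regions, that of H2AV_BOVIN, a histone H2A variant, read 31.5% ± 2.12 in Creole and 0.198% ± 0.279 in Spanish libraries, and that of the microRNA gene bta-mir-124a-2 read 64.0% ± 19.5 and 5.56% ± 7.86 (SD, n = 2 each). The quasi-likelihood test of the 76 regions measured in 2 or more libraries per group, from which these were taken, called 0 at an adjusted p of 0.05, with 15 at an unadjusted p under 0.05.

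The libraries differed in the share of cytosines with intermediate methylation. Of cytosines with at least 20 reads, 18.9% lay between 20 and 80% methylation in Creole 1, against 3.42 to 6.59% in the other libraries. From 100 to below 500 reads, 20.8% of cytosines in Creole 1 were still read as exactly 0 or 100%, and 37.2% in Spanish 2, against 81.2 to 82.4% in the other 4 libraries. In the deposited regions, 110 of 297 values of Creole 1 lay below 10% or above 90%, against 609 of 861 in the other libraries.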
